A study of Mus musculus with 28 samples.

How the data were processed

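Gene-level tables of 28 B16F10 libraries were analysed, 4 of cultured cells and 12 in each of 2 tumour tables, the first with guides against Man2a1 or Rosa26 and the second wild-type with swainsonine or PBS. Per the labels' protocols, RNA was taken up in TRIzol and libraries were made by random priming of fragmented mRNA. Per the submitters' processing notes, STAR, RSEM and the mm10 genome were used, with no versions, roles or order given. The deposited count tables held whole-number counts per gene with no scaling, 17001 genes for cultured cells and 53272 for each tumour table, of which 16999, 30598 and 30677 had a count above 0. The deposited TPM tables held transcripts scaled by the authors to a fixed total per column, over 16985, 26476 and 54087 gene symbols, and the columns of the cultured-cell table summed to 688055 to 716689, so part of its genes was not in it. Of the guide-tumour TPM columns 11 were deposited as log2(TPM + 1), although labelled TPM, and 1 on the linear scale. After back-transformation 100% of the values of the log2 columns were whole hundredths to within 1e-06 of a hundredth, so all columns were brought to the linear scale.

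Counts were used for the tests. Totals ran from 19.2 to 23.4 M counts in cultured cells, 24.8 to 39.7 M in guide tumours and 24.5 to 30.1 M in wild-type tumours, M standing for 1e+06, with 16608 to 16711, 21572 to 23250 and 20495 to 23500 genes counted. Each table was fitted alone in R 4.3.3 with edgeR 4.0.16, using filterByExpr, TMM factors and a quasi-likelihood fit of all groups of the table, and a contrast per comparison. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, out of 13313, 16021 and 16059 genes tested. Group means and standard deviations of CPM given with a log2 fold change used the TMM library sizes, while CPM of single libraries, their ranges, the Man2a1 means over 6 libraries, the list levels and the limit of the library sets used the plain column totals, so the scales differ slightly. The standard error of a log2 fold change was its absolute value over the square root of the F statistic. On simulated data in which 100 genes changed by a factor of 2 and 100 by a factor of 4, the fit recovered 86% and 100% in cultured cells, 64% and 96% in guide tumours and 32% and 90% in wild-type tumours, with 1, 10 and 4 false calls, so a change by a factor of 2 was often missed in tumours. The simulated genes were drawn independently of each other, and only genes above 1 log2 CPM were changed. Differences in cell content between tumours and library sets were not simulated. These shares can therefore be too high for the real tumours.

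Guide-tumour columns were given to samples by the description of each sample, and the bracketed number in the sample title, which gives 7 of the 12 libraries another group, was run as an alternative. By title number the 3 libraries described as Rosa26 with anti-PD-L1 are the knockout IgG group, so the comparison of knockout and Rosa26 under IgG by title number and the comparison of anti-PD-L1 and IgG in Rosa26 tumours by description use the same 6 libraries. The comparison of knockout with anti-PD-L1 and Rosa26 with IgG was also run on the 5 libraries with 1 group in both readings. The labels do not say whether replicates were separate animals or cultures, so each p measures only the spread between these samples.

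The gene lists, 27 with 485 symbols, were written before the data were examined: N-glycan processing, lysosomal, ER stress, pigmentation, interferon gamma, type I interferon, MHC class I, MHC class II, T cell, cytotoxic, checkpoint, NK, B cell, macrophage, dendritic, neutrophil, chemokine, endothelial, fibroblast, keratinocyte, muscle, adipocyte, red blood cell, G2/M, hypoxia, cholesterol and mitochondrial genes. Of the symbols, 1 was not in the tumour tables and 189 were not in the cultured-cell table. Each list was tested with camera of limma 3.58.1 with its preset correlation of 0.01, with an estimated correlation, and with fry. Members were also counted with p adjusted over the list alone. In each comparison the genes named are Man2a1 and Man2a2, a fixed set of key immune and melanoma genes, the members with the smallest p of each list described (at most 4), and up to 8 genes per direction with the smallest adjusted p, an absolute log2 fold change of at least 1, a mean log2 CPM of at least 1 and complete separation of the groups. Where none was called, up to 3 genes per direction with the smallest unadjusted p are given as values.

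Alternatives were DESeq2 1.42.0, relative log expression size factors, no filter on low counts, an absolute log2 fold change of at least 1, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) over the genes with a symbol in both tables, leaving out each library in turn, a replicate block, and a fit of only the 2 groups compared. After the data were seen, further alternatives were added: library sets as a covariate and protein-coding genes alone (GENCODE M21, mitochondrial genes left out). The library sets rest on more than 5 CPM of Gm10175 (set P) or Gm6988 (set Q) or of neither (set R). Guide tumours held 1, 5 and 6 libraries of sets P, Q and R, and wild-type tumours 3 of set P, which are the combination group, and 9 of set Q. The difference between libraries labelled knockout and Rosa26 was compared with the effect of swainsonine by correlation across genes, which are not independent replicates. Its values by title number in the IgG arms and over the genes past the threshold were added after the data were seen. The fits were tested on simulated data in which fold changes were known. Samples were regrouped in all other splits of each pair of groups to count calls by chance. For the interactions 60 groupings were used, the real one and others drawn at random, not all that are possible. No column was left without a sample, and raw reads were not used here.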

Results

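RNA was sequenced from 28 libraries of the mouse melanoma line B16F10, 4 from cultured cells and 24 from tumours. The cultured cells carried a guide against Man2a1 or against the Rosa26 locus (n = 2 per group, 19.2 to 23.4 M counts per library, M standing for 1e+06). In 12 tumours these guides were crossed with anti-PD-L1 or IgG antibody (n = 3 per group, 24.8 to 39.7 M counts). In 12 wild-type tumours swainsonine or PBS was crossed with the same antibodies (n = 3 per group, 24.5 to 30.1 M counts). Man2a1 encodes Golgi alpha-mannosidase II, an enzyme of N-glycan processing that swainsonine inhibits, and anti-PD-L1 blocks the ligand encoded by Cd274. Differences are given as log2 ± standard error, and levels as CPM (counts per M counts), mean ± standard deviation.

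Was Man2a1 lower in the samples labelled knockout? In cultured cells Man2a1 stood at 51.1 and 36.9 CPM in the 2 knockout libraries and at 145 and 144 CPM in the 2 Rosa26 libraries. In the guide tumours the labels gave 2 readings, because the description and the bracketed number in the title of each sample put 7 of the 12 libraries in different groups and 5 in the same group. By description, Man2a1 was 111, 94.4 and 116 CPM in the libraries labelled Rosa26 with IgG, 26.2, 33.4 and 59.0 CPM in those labelled Rosa26 with anti-PD-L1, 98.6, 125 and 34.7 CPM in those labelled knockout with IgG, and 89.1, 37.0 and 51.7 CPM in those labelled knockout with anti-PD-L1. The libraries labelled knockout by description therefore held 72.6 ± 36.8 CPM of Man2a1 and those labelled Rosa26 held 73.2 ± 39.1 CPM (n = 6 each). By title number Man2a1 was 40.3 ± 12.4 CPM in the libraries labelled knockout (26.2 to 59.0) and 106 ± 13.7 CPM in those labelled Rosa26 (89.1 to 125), with no overlap. Wild-type tumours held 126, 118 and 129 CPM of Man2a1 with IgG and PBS, 85.1, 136 and 107 CPM with anti-PD-L1, 122, 65.7 and 88.7 CPM with swainsonine, and 81.9, 104 and 37.8 CPM with both. The guide-tumour comparisons follow the description, with the title number reading beside each, and 5 libraries that both readings place alike are also compared alone.

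**Figure D1:**
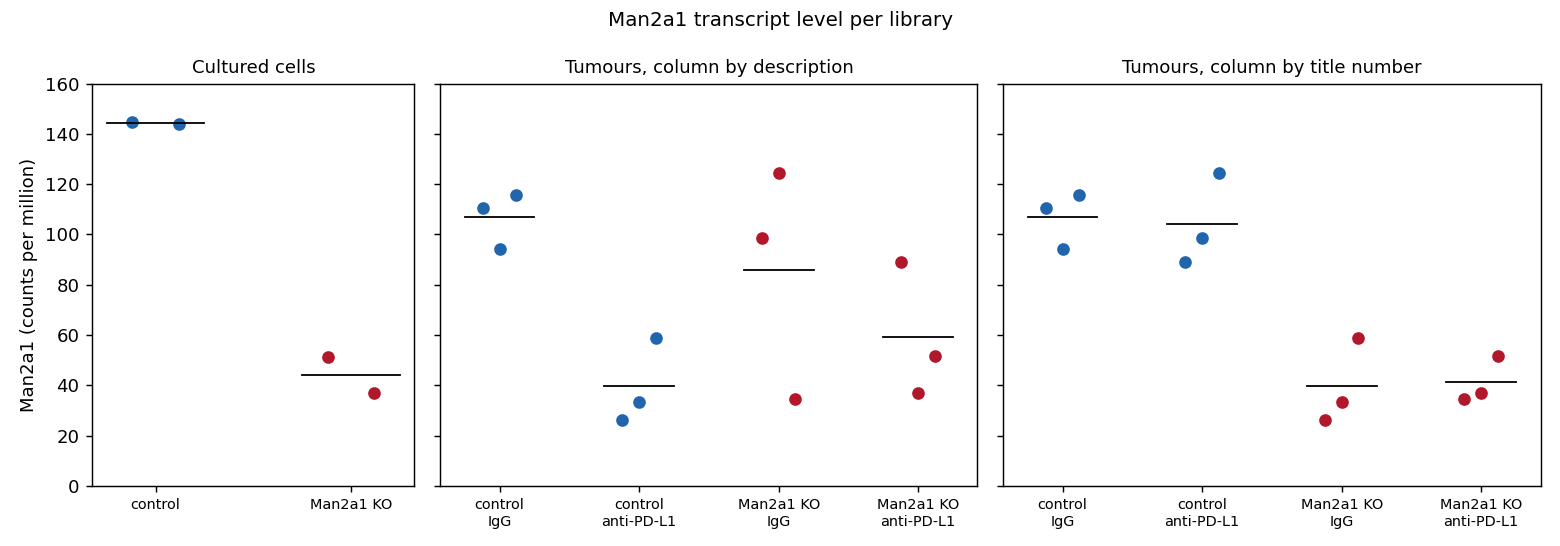
Man2a1 CPM (y axis) per group in cultured cells, in guide tumours grouped by description and in guide tumours grouped by title number. Points are libraries and lines are group means.

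Which transcripts differed between knockout and Rosa26 cells in culture? Man2a1 differed most clearly, at -1.74 ± 0.16 (43.7 ± 10.3 against 146 ± 0.80 CPM, n = 2 each), while Man2a2, which encodes the related Golgi enzyme, differed by -0.05 ± 0.15. Selenbp1 stood at 27.8 ± 6.78 against 93.8 ± 11.3 CPM (-1.76 ± 0.18) and Higd1a at 31.2 ± 2.76 against 59.6 ± 2.97 CPM (-0.94 ± 0.11). Sulf2, which encodes an extracellular sulfatase, stood at 82.3 ± 1.202 against 51.8 ± 5.79 CPM (0.67 ± 0.11). The hypoxia response list was lower in knockout cells, with 18 of 19 genes below 0 and a median of -0.67. It was led by Adm (-1.87 ± 0.23), Bnip3 (-1.59 ± 0.24), Vegfa (-1.26 ± 0.20) and Car9 (-2.01 ± 0.31), which HIF1 induces when oxygen is short. Melanocyte pigmentation genes had a median of -0.29 with Tyr at -0.54 and Dct at -0.29. The list level was 8.50 and 8.49 (mean log2 CPM) in knockout and 8.95 and 8.57 in Rosa26 libraries. Tyr stood at 868 and 503 CPM in the Rosa26 libraries against 488 and 468 CPM in knockout, and Dct at 5883 and 4613 against 4263 and 4456 CPM. H2-K1 of MHC class I stood at 12.7 ± 1.43 against 35.1 ± 11.9 CPM (-1.48 ± 0.24). By camera the hypoxia list had adjusted p = 4.73e-13 and the pigmentation list adjusted p = 0.000606, each with adjusted p = 0.716 with an estimated correlation. Over all genes 0 of the 19 hypoxia genes were called, and 16 when adjusted over the list alone. No gene passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05 (0 genes, 1332 at unadjusted p under 0.05), and DESeq2 called 69. Man2a1 was at adjusted p = 0.164 by edgeR and 3.31e-20 by DESeq2. Leaving out a library left an arm of 1, with the spread taken from the other pair alone, and gave 15 and 38 genes without knockout replicates 1 and 2 and 201 and 4125 without Rosa26 replicates 1 and 2. These counts therefore do not test the result.

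What differed between knockout and Rosa26 tumours under IgG? Among the libraries labelled by description, Gm6988, a processed pseudogene, stood at 16.1 ± 1.76 against 0.874 ± 0.526 CPM (4.18 ± 0.77). In the same libraries mt-Nd4l stood at 8.49 ± 0.24 against 1.13 ± 0.15 CPM (2.91 ± 0.52), and Sox4 differed by -0.67 ± 0.13 (n = 3 each). Cholesterol synthesis genes were lower in the libraries labelled knockout (19 of 20 below 0, median -0.36), with Srebf2, the master regulator of the pathway, at -0.63 ± 0.15. Transcripts of the mitochondrial genome were higher (12 of 13 above 0, median 0.53). These differences moved with the library sets that Gm6988 marks, since all 3 libraries labelled knockout carried more than 5 CPM of Gm6988 and no library labelled Rosa26 did. By title number, Man2a1 differed by -1.41 ± 0.26 (40.1 ± 17.5 against 107 ± 11.8 CPM). Sulf2 differed by 0.69 ± 0.14, with the sign seen in culture, and the hypoxia list had a median of -0.57 with 19 of 19 genes below 0. By camera the cholesterol list had adjusted p = 6.31e-06 and the mitochondrial list adjusted p = 1.98e-05 by description, each with adjusted p = 0.992 with an estimated correlation. In all 0 genes of either were called over all genes, and 5 and 6 when adjusted over the list alone. With the library set as a covariate the cholesterol list had adjusted p = 0.200 and the mitochondrial list changed sign at adjusted p = 0.189 (camera). By title number the cholesterol list changed sign at adjusted p = 0.778. The hypoxia list by title number had adjusted p = 1.44e-07 by camera, and adjusted p = 0.868 with an estimated correlation. At a Benjamini-Hochberg adjusted p of 0.05, edgeR's quasi-likelihood test called no gene (0 genes, 2515 at unadjusted p under 0.05), and DESeq2 called 500. Fitting with no filter gave 3 and a fit of the 2 groups alone gave 31. By title number edgeR called 0 (504 at unadjusted p under 0.05) and DESeq2 called 5.

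What differed between knockout and Rosa26 tumours under anti-PD-L1? By description, interferon gamma response genes were higher in the libraries labelled knockout (25 of 25 above 0, median 2.99, n = 3 each). The T cell chemoattractant Cxcl9 stood at 27.0 ± 20.1 against 3.07 ± 2.12 CPM (3.14 ± 0.94) and Irf1 at 1.80 ± 0.51. MHC class I presentation had a median of 1.66, with H2-K1 at 366 ± 224 against 101 ± 40.2 CPM (1.86 ± 0.52), and Cd274 differed by 0.95 ± 0.43. The high values lay in knockout replicates 2 and 3, with Cd274 at 31.8 and 26.8 CPM against 6.34 CPM in replicate 1, and Irf1 at 84.3 and 70.2 against 13.9 CPM. T cell markers (median 1.40 over the 8 of 22 genes measured) were higher as well. Skeletal muscle markers had a median of 3.55, or 0.62 without knockout replicate 3, which held Acta1 at 256 CPM against 7.40 and 6.86 in the other 2. Red blood cell markers had a median of -3.28, or -1.73 without the library labelled Rosa26 replicate 2 by description, which held Hbb-bs at 9380 CPM. By title number the same comparison gave interferon gamma response 3.60, T cell markers 1.84 (8 of 22 genes measured) and cytotoxic effectors 4.08 (6 of 18 measured). Cd274 stood at 23.3 ± 10.8 against 7.87 ± 1.18 CPM (1.56 ± 0.32) and Man2a1 differed by -1.36 ± 0.26, against 0.58 ± 0.45 by description. The same 2 libraries held the high values, and the other library of that group had 1.01 CPM of Cxcl9. By camera, the description gave adjusted p = 4.92e-12 for interferon gamma response, 8.11e-10 for MHC class I, 0.000404 for T cell markers, 7.49e-05 for muscle and 3.03e-08 for red blood cells, each with adjusted p = 0.654 with an estimated correlation. By title number interferon gamma response had adjusted p = 2.07e-21 by camera, T cell markers 4.08e-06 and cytotoxic effectors 3.29e-07, each with adjusted p = 0.154 with an estimated correlation. By fry these had adjusted p = 0.0437, 0.0309 and 0.0309. By title number 9 lists passed fry, and 0 did with the library set as a covariate. Of 25 interferon gamma genes 0 were called over all genes, and 22 by description and 25 by title number when adjusted over the list alone. The quasi-likelihood test of edgeR called no gene at a Benjamini-Hochberg adjusted p of 0.05 in either reading (0 genes, 1151 at unadjusted p under 0.05 by description and 1570 by title number). DESeq2 called 0 by description and 222 by title number. Leaving out knockout replicate 2 by description gave 88 genes and leaving out replicate 1 gave 1. On log2(TPM + 1) the median over all genes was 0.10 higher, or 0.13 on log2(TPM + 0.1).

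What did anti-PD-L1 change in Rosa26 tumours? By description, Man2a1 itself differed by -1.41 ± 0.46 between the libraries labelled Rosa26 with anti-PD-L1 and those labelled Rosa26 with IgG (n = 3 each). By title number these same libraries compare knockout with Rosa26 under IgG. The differences by description here are thus those given by title number for that comparison. Whether they belong to antibody or guide depends on which label is right. Man2a1 stood at 26.2, 33.4 and 59.0 CPM in the libraries described as anti-PD-L1, below the lowest IgG control at 94.4 CPM. Cultured knockout cells held 51.1 and 36.9 CPM. For Man2a1 these values go with the guide and argue against the description, so the differences below may not be effects of anti-PD-L1. The hypoxia response was lower (19 of 19 below 0, median -0.57), muscle markers higher (13 of 13 above 0, median 1.82) and the interferon gamma response higher (median 0.61). Ccng1, a p53 target, differed by 0.70 ± 0.12 and Coq8a by 1.03 ± 0.23. The vascular smooth muscle and pericyte genes Ednra and Notch3 differed by -1.64 ± 0.37 and -0.95 ± 0.22. By title number, mitochondrial genome transcripts were higher (median 0.999), with mt-Nd4l at 2.99 ± 0.50, and Man2a1 differed by -0.03. The title-number libraries labelled anti-PD-L1 all carried Gm6988 above 5 CPM and the 3 labelled IgG did not. By camera, the description gave adjusted p = 9.60e-08 for hypoxia and 5.11e-06 for muscle, each with adjusted p = 0.946 with an estimated correlation. It gave adjusted p = 0.00266 for interferon gamma response, with adjusted p = 0.952 with an estimated correlation. By title number, hypoxia and interferon gamma response both had adjusted p = 0.596, the latter with the other sign. Mitochondrial transcripts had adjusted p = 2.50e-09 by camera and adjusted p = 0.925 with an estimated correlation. The interferon gamma call by description was lost without Rosa26 IgG replicate 1 (adjusted p = 0.230) or replicate 2 (adjusted p = 0.151), and without anti-PD-L1 replicate 1 (adjusted p = 0.157). No gene passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05 in either reading (0 genes, 577 at unadjusted p under 0.05 by description and 2402 by title number), and DESeq2 called 1 and 518. With limma on log2(TPM + 1) the median over all genes was 0.19 lower, or 0.23 on log2(TPM + 0.1).

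What did anti-PD-L1 change in knockout tumours? By description, interferon gamma response genes were higher in the libraries labelled knockout with anti-PD-L1 than in those labelled knockout with IgG (25 of 25 above 0, median 3.37, n = 3 each). Cxcl9 stood at 27.0 ± 20.1 against 0.790 ± 0.641 CPM (5.09 ± 1.06). The high values lay in anti-PD-L1 replicates 2 and 3, with Irf1 at 84.3 and 70.2 CPM and H2-K1 at 517 and 471 CPM, against 13.9 and 106 CPM in replicate 1. MHC class I (median 1.84, H2-K1 1.97 ± 0.53) and MHC class II (median 3.16), which present antigen to CD8 and CD4 T cells, were higher too. So was cholesterol synthesis (20 of 20 above 0, median 0.47, Mvk 0.64 ± 0.16, Mvd 0.84 ± 0.21). Muscle markers were higher as well (median 4.99, Acta1 6.94 ± 1.40), with Acta1 at 256 CPM in knockout anti-PD-L1 replicate 3. By title number, interferon gamma response (median 2.99), T cell markers (1.69, 8 of 22 genes measured) and cytotoxic effectors (2.80, 6 of 18 measured) were higher and red blood cell markers lower (-3.42). Their adjusted p by camera was 6.67e-12, 5.91e-06, 3.08e-05 and 5.44e-08, and with an estimated correlation 0.358, 0.298, 0.325 and 0.325. Cholesterol synthesis changed sign (adjusted p = 0.0354 by camera, and adjusted p = 0.729 with an estimated correlation). By camera, the description gave adjusted p = 5.75e-18 for interferon gamma response, 1.96e-11 for MHC class I, and 1.20e-11 for both muscle and cholesterol synthesis, each with adjusted p = 0.398 with an estimated correlation. MHC class II had adjusted p = 7.25e-06 by camera, with adjusted p = 0.418 with an estimated correlation. Over all genes none of these lists held a called gene. When adjusted over the list alone, 25 of 25 interferon gamma genes, 15 of 18 MHC class I genes and 11 of 20 cholesterol genes were called. At a Benjamini-Hochberg adjusted p of 0.05, edgeR's quasi-likelihood test called no gene by description (0 genes, 1587 at unadjusted p under 0.05), and DESeq2 called 118. Fitting with no filter gave 41, and leaving out anti-PD-L1 replicate 1 gave 35 and knockout IgG replicate 1 gave 1. By title number edgeR called 1 gene, the noncoding Gm20619 (-1.24 ± 0.15, 4.75 ± 0.58 against 11.2 ± 0.17 CPM, n = 3 each, adjusted p = 0.0426), and DESeq2 called 115.

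What separated knockout tumours under anti-PD-L1 from Rosa26 tumours under IgG? Only 5 libraries of these groups kept the same group in both readings, 2 of knockout with anti-PD-L1 and 3 of Rosa26 with IgG. In them Man2a1 stood at 44.3 ± 9.68 against 107 ± 11.98 CPM (-1.28 ± 0.17, adjusted p = 0.146 by edgeR). In these 5 libraries interferon gamma response genes were higher with a median of 3.50 (25 of 25 above 0). Irf1 was at 2.53 ± 0.22, Nlrc5 at 3.50 ± 0.37 and Cxcl9 at 38.6 ± 2.48 against 1.09 ± 0.985 CPM (5.12 ± 0.61). Cd8a, which marks cytotoxic T cells, stood at 1.87 ± 0.443 against 0.0850 ± 0.0869 CPM. H2-K1 was at 494.0 ± 40.8 against 108 ± 33.1 CPM (2.20 ± 0.27), and B2m at 1447 ± 67.6 against 302 ± 145 CPM (2.26 ± 0.36). Cd274 was at 29.3 ± 4.01 against 10.8 ± 1.84 CPM (1.44 ± 0.18). Red blood cell markers (-2.83) and hypoxia genes (-0.48, 19 of 19 below 0) were lower, although the hypoxia list level of Rosa26 replicate 3 (6.92) was as low as in the knockout libraries (7.06 and 6.93). Muscle markers had a median of 5.53, which rests on knockout replicate 3, where their list level was 4.42 against 0.77 in replicate 2. The immediate early gene Egr1 (chromosome 18, 34859823 to 34864984, mm10) was the 1 gene called by edgeR's quasi-likelihood test, at 2.34 ± 0.14 (38.9 ± 1.19 against 7.66 ± 0.896 CPM, Benjamini-Hochberg adjusted p = 0.0348, all 2 above all 3). By camera in the 5 libraries, interferon gamma response had adjusted p = 9.02e-31, with adjusted p = 0.342 with an estimated correlation and adjusted p = 0.0914 by fry. Red blood cell markers had adjusted p = 1.11e-09, with adjusted p = 0.342 with an estimated correlation, and muscle markers 6.89e-07, with adjusted p = 0.418 with an estimated correlation. Hypoxia had adjusted p = 7.26e-05, with adjusted p = 0.722 with an estimated correlation. Over all genes 0 interferon gamma genes were called, and 25 of 25 when adjusted over the list alone, as were 12 of 16 T cell markers and 8 of 10 cytotoxic effectors. The count filter follows the smallest group, here 2, so genes expressed in only the 2 knockout libraries could enter. In the fit of all guide tumours 8 T cell markers and 6 cytotoxic effectors were measured. The counts of 12 and 8 are therefore favoured by the filter. With 3 libraries per group by description, interferon gamma response had a median of 3.05 (camera, adjusted p = 1.27e-15, and adjusted p = 0.394 with an estimated correlation). There edgeR called 0 genes (1906 at unadjusted p under 0.05), and DESeq2 139. Fitting with no filter gave 30, against 27 without knockout replicate 1 and 149 without replicate 2. By title number edgeR called 0 (1765 at unadjusted p under 0.05) and DESeq2 called 247. On log2(TPM + 0.1) the median over all genes was 0.11 lower by description.

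Did the response to anti-PD-L1 differ between knockout and Rosa26 tumours? By description, the difference of differences was positive for interferon gamma response (25 of 25 above 0, median 2.86, Cxcl9 3.60 ± 1.36), MHC class I (median 1.78, H2-K1 2.06 ± 0.73), type I interferon response (median 1.14) and cholesterol synthesis (20 of 20 above 0, median 0.43). It was negative for mitochondrial genome transcripts (13 of 13 below 0, median -0.38). Markers of other tissues moved as far, with Acta1 of muscle at 4.10 ± 1.92 and the red cell genes at a median of -2.53 (8 of 8 below 0, Hbb-bs -3.17 ± 1.53). Interferon gamma from activated T cells induces MHC class I and Cxcl9 in tumour and myeloid cells. By title number it was also positive for interferon gamma response (2.98), type I interferon response (1.97) and MHC class I (2.12). Their adjusted p by camera was 2.55e-10, 3.96e-16 and 1.54e-08, and with an estimated correlation 0.353, 0.234 and 0.310. Cholesterol synthesis changed sign (adjusted p = 0.884 by camera). By camera, the description gave adjusted p = 1.59e-10 for interferon gamma response, 2.90e-10 for cholesterol synthesis, 3.32e-08 for MHC class I, 1.30e-05 for type I interferon response, 0.000421 for mitochondrial transcripts and for muscle, and 0.00142 for red blood cells, each with adjusted p = 0.513 with an estimated correlation. With the library set as a covariate the mitochondrial list had adjusted p = 0.796, and it lost its call without Rosa26 IgG replicate 1 (adjusted p = 0.0772). Without knockout anti-PD-L1 replicate 3 the muscle and red blood cell lists lost theirs (adjusted p = 0.358 and 0.0947), and by title number muscle had 0.939. The quasi-likelihood test of edgeR called no gene at a Benjamini-Hochberg adjusted p of 0.05 in either reading (0 genes, 388 at unadjusted p under 0.05 by description and 895 by title number). DESeq2 called 0 and 2. On log2(TPM + 1) the median over all genes was 0.17 higher by description, or 0.20 on log2(TPM + 0.1).

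What did anti-PD-L1 alone change in wild-type tumours? T cell markers were higher (21 of 21 above 0, median 2.01, Cd247 2.69 ± 0.98, Cd3g 3.21 ± 1.26). So were cytotoxic effectors (median 2.43), with Gzmb, the granule protease of killer cells, at 3.40 ± 4.14 against 0.290 ± 0.307 CPM (3.52 ± 1.67, n = 3 each). The hypoxia response was also higher (19 of 19 above 0, median 0.76, Aldoa 1.05 ± 0.40, Hk2 0.59 ± 0.23). In contrast, ER stress genes (median -0.27, Dnajb9 -0.87 ± 0.27) and N-glycan processing genes (20 of 25 below 0, median -0.21) were lower. Man2a2 stood at 50.7 ± 10.04 against 86.1 ± 8.55 CPM (-0.76 ± 0.19), and Man2a1 differed by -0.15 ± 0.28. Rab6b differed by -0.73 ± 0.13 and Baiap2 by 0.81 ± 0.17 (31.7 ± 2.25 against 18.1 ± 3.04 CPM). Anti-PD-L1 replicate 3 stood apart from the other anti-PD-L1 tumours, with Cxcl9 at 0.583 CPM against 94.0 and 43.1 CPM and Gzmb at 0.156 against 8.15 and 2.08 CPM. By camera, adjusted p was 1.36e-06 for T cell markers, 7.48e-06 for cytotoxic effectors, 2.07e-07 for hypoxia, 0.000224 for ER stress and 0.00134 for N-glycan processing, each with adjusted p = 0.779 with an estimated correlation. Interferon gamma response had a median of 2.07 (camera, adjusted p = 0.000704, with adjusted p = 0.840 with an estimated correlation), and without anti-PD-L1 replicate 1 adjusted p was 0.620. Over all genes 0 genes of these lists were called, and when adjusted over the list alone 0 T cell markers, 0 hypoxia genes and 1 N-glycan gene, Man2a2. No gene passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05 (0 genes, 823 at unadjusted p under 0.05), and DESeq2 called 4.

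What did swainsonine alone change in wild-type tumours? Hypoxia response genes were higher (19 of 19 above 0, median 0.85), with the glycolysis and glucose uptake genes Hk2 at 0.85 ± 0.24 and Slc2a1 at 1.51 ± 0.46, Ero1l at 1.88 ± 0.54 and Bnip3 at 1.30 ± 0.39 (n = 3 each). Melanocyte pigmentation genes were lower (19 of 20 below 0, median -0.47, Rab27a -0.55 ± 0.21, Slc45a2 -0.53 ± 0.22, Tyr -0.50 ± 0.24). So were N-glycan processing genes (median -0.21, Man2a1 -0.39 ± 0.28, Man2a2 -0.50 ± 0.19) and ER stress genes (median -0.23). Neutrophil markers (median 1.29, S100a9 2.13 ± 0.92) and red blood cell markers (median 1.74, Slc4a1 2.29 ± 0.77) were higher. Of single genes, Eva1a stood at 2.03 ± 0.29 against 7.10 ± 0.51 CPM (-1.80 ± 0.24) and Kbtbd11 at 58.1 ± 6.51 against 30.6 ± 0.89 CPM (0.93 ± 0.14). Pgf, which encodes an angiogenic growth factor, differed by 3.04 ± 0.67. By camera, hypoxia had adjusted p = 6.47e-16, pigmentation 9.20e-09, N-glycan processing 0.000180 and neutrophil markers 0.00183, each with adjusted p = 0.453 with an estimated correlation. Red blood cell markers had adjusted p = 0.000579 by camera and adjusted p = 0.762 with an estimated correlation. ER stress had adjusted p = 4.46e-05 and adjusted p = 0.658 with an estimated correlation. The swainsonine tumours stood apart from each other, with Cxcl9 at 2.72, 0 and 48.9 CPM and Hbb-bs at 3658, 8175 and 1039 CPM. Without swainsonine replicate 2 the lists called higher by camera went from 3 to 15, and without IgG and PBS replicate 1 to 7. The red blood cell call was lost without IgG and PBS replicate 1 (adjusted p = 0.0530) or swainsonine replicate 1 (adjusted p = 0.0617), and the ER stress call without swainsonine replicate 3 (adjusted p = 0.112). Over all genes 0 hypoxia genes were called, and 16 of 19 when adjusted over the list alone. At a Benjamini-Hochberg adjusted p of 0.05, edgeR's quasi-likelihood test called no gene (0 genes, 860 at unadjusted p under 0.05), and DESeq2 called 18. On the TPM scale limma on log2(TPM + 1) called 1, with the median over all genes 0.11 lower (0.14 lower on log2(TPM + 0.1)).

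What did anti-PD-L1 with swainsonine change against IgG and PBS? Genes of T cells and killer cells rose, with Cd3e at 2.20 ± 1.24 against 0.0867 ± 0.0428 CPM (4.59 ± 1.24, adjusted p = 0.0292) and Cd4 at 2.99 ± 1.59 against 0.412 ± 0.384 CPM (2.84 ± 0.82, adjusted p = 0.0377). Gzmb rose to 17.7 ± 9.78 from 0.290 ± 0.307 CPM (5.89 ± 1.79, adjusted p = 0.0455). Prf1, which encodes the pore that lets granzymes into target cells, rose to 14.3 ± 9.85 from 0.229 ± 0.301 CPM (5.92 ± 1.82, adjusted p = 0.0475). For each of these 4 genes all 3 combination tumours stood above all 3 controls, and the test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cxcl10 rose to 129 ± 43.3 from 28.1 ± 5.08 CPM (2.20 ± 0.59, adjusted p = 0.0297), and Ifng stood at 0.765 ± 0.316 against 0.0237 ± 0.0411 CPM (adjusted p = 0.0497). The checkpoint and regulatory T cell genes Lag3 (3.76 ± 0.68, adjusted p = 0.00687), Tnfrsf4 (2.38 ± 0.45) and Foxp3 (3.25 ± 0.71) rose. So did the cross-presenting dendritic cell genes Batf3 (2.16 ± 0.52) and Xcr1 (5.57 ± 1.45). Cd8a was 10.01 ± 4.97 against 0.435 ± 0.493 CPM at adjusted p = 0.0646, Cd274 50.0 ± 5.96 against 11.1 ± 6.12 CPM at adjusted p = 0.0806 and Mki67 differed by -1.59 ± 0.53 at adjusted p = 0.0624. None of the 3 passed. The ER chaperone genes Hsp90b1 (-1.20 ± 0.21) and Dnajc3 (-0.88 ± 0.19) fell. So did Man1a2 (-0.89 ± 0.16), Mgat4a (-0.80 ± 0.19) and Slc35a1 (-0.57 ± 0.14) of N-glycan processing and Kif11 (-0.88 ± 0.17) and Hmmr (-1.18 ± 0.25) of mitosis. These 2 lists as a whole did not move, with medians of 0.012 and -0.047. Of 25 N-glycan genes 0 were called higher and 3 lower, and of 21 G2/M genes 1 higher and 4 lower. Man2a1 differed by -0.65 ± 0.28 (76.2 ± 29.2 against 120 ± 4.59 CPM, adjusted p = 0.129), Man2a2 by -0.46 ± 0.19 and Man2b1 by 0.65 ± 0.22. In all, 1028 genes were higher and 1529 lower (2557 of 16059, 5478 at unadjusted p under 0.05). This stood against 1979 and 1876 by DESeq2 and 974 by limma on log2(TPM + 1). Leaving out IgG and PBS replicates 1, 2 and 3 gave 1297, 1117 and 598. The count moved without combination replicate 1 to 846 and without combination replicate 3 to 3972. A replicate block gave 1667. The combination libraries all belong to set P and the IgG and PBS libraries all to set Q. Treatment and library set therefore cannot be told apart in any of these differences.

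The combination libraries also stood apart in pseudogenes. All 3 carried Gm10175, a transcribed processed pseudogene (chromosome 7, 23946646 to 23947290, mm10), at 6.90, 10.4 and 25.6 CPM (7.41 ± 0.75). They held Gm6988 (chromosome 12, 110315990 to 110316364, -6.22 ± 0.38) at only 0.133, 0.145 and 0.204 CPM, against 8.92 to 19.1 CPM in the 9 other wild-type libraries, and were low in AC161763.1 too (-9.88 ± 0.46). The mitochondrial transcript mt-Atp8 stood at 1136, 360 and 2040 TPM in them and at 4315 TPM in Rosa26 IgG replicate 1, also of set P. All other tumour libraries held 5.689e+04 to 1.326e+05 TPM. The descriptions of the combination libraries end in A, as do those of the guide tumours and of no other wild-type library. Rosa26 IgG replicate 1 was also the only guide-tumour column deposited on the linear TPM scale. Among guide tumours the total counts of the sets did not overlap, at 25.4 to 26.3 M in set Q and 32.4 to 39.7 M in set R. Whether the combination libraries were prepared or processed apart was not tested. Of 993 pseudogenes tested 216 were called (21.8%), and of 13253 protein-coding genes 2200 (16.6%). Calls on pseudogenes are uncertain, since reads shared with related genes were not measured here, among them Gm12261 (-4.42 ± 0.34), Gm5869 (-3.00 ± 0.30), Gm45855 (2.54 ± 0.27), Gm9616 (1.80 ± 0.18), Gm1821 (1.75 ± 0.17), Gm13509 (1.16 ± 0.13) and Rps10-ps2 (1.93 ± 0.25). With protein-coding genes only, 2223 genes were called. Among protein-coding genes with the smallest adjusted p by edgeR, the muscle and glycolysis gene Eno3 rose to 47.6 ± 4.69 from 20.3 ± 3.68 CPM (1.23 ± 0.16, adjusted p = 0.00179). Kbtbd11 rose to 65.6 ± 7.43 from 30.6 ± 0.89 CPM (1.10 ± 0.14, adjusted p = 0.00199), and the nucleoporin gene Ranbp2 fell to 37.6 ± 2.22 from 94.0 ± 5.47 CPM (-1.32 ± 0.13, adjusted p = 0.000816). Rif1 (-1.79 ± 0.17), Htatsf1 (-1.24 ± 0.12) and Snx13 (-1.21 ± 0.12) fell too, each with all 3 combination tumours below all 3 controls. Combination replicate 3 held 13.4% of counts in mitochondrial genes, against 3.58% and 2.63% in the other combination libraries, and combination replicate 2 held 244 CPM of the muscle actin Acta1.

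Across the gene lists of the combination against IgG and PBS, T cell markers had a median of 4.201 (15 of 21 called over all genes, 20 when adjusted over the list alone) and cytotoxic effectors 4.70 (14 and 16 of 17). NK cell markers had a median of 4.17 (3 and 3 of the 3 measured, out of 10 listed) and checkpoints 2.75 (4 and 9 of 15). By camera the adjusted p of these 4 lists, in the order given, was 1.09e-10, 1.72e-09, 0.00502 and 1.37e-05, each with adjusted p = 0.546 with an estimated correlation. By fry it was 0.0416 for the first 3 and 0.0489 for checkpoints. With a replicate block 0 lists passed fry. The same held without any single IgG and PBS library and without combination replicates 1 or 2, while 8 lists passed without combination replicate 3. Interferon gamma response had a median of 3.76 (5 and 8 of 27, camera 6.20e-08), MHC class I 2.62 (5 and 13 of 18, 2.43e-06) and MHC class II 3.81 (0 and 8 of 10, 0.000420). Dendritic cell markers had a median of 2.29 (4 and 5 of 10, 0.00476), T cell recruiting chemokines 2.81 (4 and 5 of 10, 0.000420) and endothelial markers 0.71 (2 and 4 of 17, 0.00461), and red blood cell markers -3.28 (4 and 8 of 8 lower, 0.000420). All 7 of these lists had adjusted p = 0.546 with an estimated correlation. Red cells, which fill tumour vessels, thus differed in the other direction from Eng (1.03 ± 0.22) and Plvap (1.17 ± 0.28) of the endothelium. Type I interferon response had a median of 2.25 (2 and 0 of 26, camera 1.48e-06, adjusted p = 0.552 with an estimated correlation). Macrophage markers had a median of 2.22 (1 and 0 of 21, 0.000302), lysosomal genes 0.27 (5 and 6 of 33 higher, 0.00534) and ER stress -0.33 (4 and 5 of 24 lower, 0.0119), each with adjusted p = 0.609 with an estimated correlation. Fibroblast genes had a median of 0.56 (1 and 0 of 17, camera 0.0119, adjusted p = 0.667 with an estimated correlation). Mitochondrial transcripts had a median of -0.33 (2 and 2 of 13 lower, 0.00998, adjusted p = 0.653 with an estimated correlation) and hypoxia 0.41 (1 and 0 of 19, 0.0265, adjusted p = 0.754 with an estimated correlation). Lists past no threshold by camera were B cells (median 0.58, adjusted p = 0.438), neutrophils (0.34, 0.486), keratinocytes (-0.12, 0.880) and muscle (4.23, 0.0629). So were adipocytes (1.58, 0.282), N-glycan processing (0.01, 0.485), cell cycle G2/M (-0.05, 0.485), cholesterol synthesis (0.21, 0.159) and pigmentation (0.04, 0.932). The endothelial call was lost without combination replicate 2 (adjusted p = 0.0705), the ER stress call without replicate 3 (adjusted p = 0.0551), the lysosomal call without replicate 1 (adjusted p = 0.0614). The mitochondrial call was lost without replicates 1 or 2 (adjusted p = 0.0533 and 0.138) and the hypoxia call without replicates 1 or 3 (adjusted p = 0.0614 and 0.0771). The fibroblast call was lost without IgG and PBS replicate 2 (adjusted p = 0.102) or combination replicate 2 (adjusted p = 0.133).

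**Figure D2:**
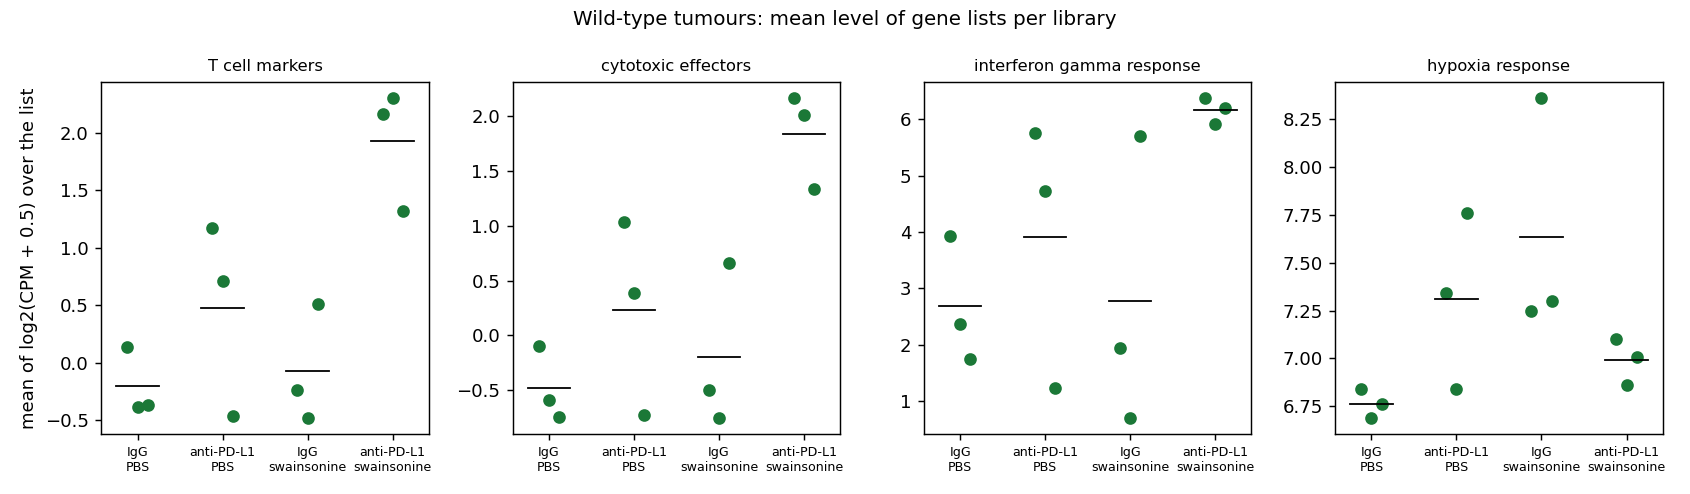
Mean log2(CPM + 0.5) over the list (y axis) for T cell markers, cytotoxic effectors, interferon gamma response and hypoxia response in the 4 wild-type groups. Points are libraries and lines are group means, and T cell markers stood at 2.16, 2.30 and 1.32 in the combination group against 0.14, -0.39 and -0.37 with IgG and PBS.

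What did the combination add to anti-PD-L1 alone? T cell markers were higher (21 of 21 above 0, median 2.14) and cytotoxic effectors higher (median 2.38), though Cd4 (2.14 ± 0.79, adjusted p = 0.114), Cd8a (2.54 ± 1.37) and Gzmb (2.38 ± 1.46) did not pass edgeR alone (n = 3 each). Anti-PD-L1 replicate 3 lowered the reference group, with Cd3e and Cd8a at 0 CPM and Gzmb at 0.156 CPM. For Cd3e the groups overlapped, at 1.05 CPM in anti-PD-L1 replicate 1 and 0.693 CPM in combination replicate 3. For Cd8a they came close without overlap, at 3.30 and 3.71 CPM in the same libraries. The T cell checkpoint gene Lag3 rose by 2.58 ± 0.64 (adjusted p = 0.0362). The endothelial genes Cdh5 (0.93 ± 0.23), Robo4 (1.06 ± 0.27) and Eng (0.86 ± 0.22) rose. The mitotic genes Bub1 (-0.94 ± 0.18), Hmmr (-1.21 ± 0.25) and Kif11 (-0.79 ± 0.17) fell, and so did Hsp90b1 (-1.04 ± 0.21). Sox10, which specifies melanocytes, rose by 0.61 ± 0.16. Htatsf1 (-1.21 ± 0.12, adjusted p = 0.00128) and Snx13 (-1.11 ± 0.12, adjusted p = 0.00147) fell, all 3 below all 3. Beside them stood the pseudogenes Gm6988 (-6.48 ± 0.38), Rps12-ps3 (2.97 ± 0.46), Gm14681 (-2.58 ± 0.27), Gm4617 (-1.32 ± 0.16) and Gm4459 (2.05 ± 0.30), whose calls are uncertain. By camera adjusted p was 6.26e-07 for T cell markers, 2.02e-06 for cytotoxic effectors, 0.00190 for endothelial markers (median 0.88) and 0.0173 for G2/M (median -0.19), each with adjusted p = 0.596 with an estimated correlation. Over all genes 0 of 21 T cell markers, 3 of 17 endothelial and 3 of 21 G2/M genes were called, and 0, 6 and 5 when adjusted over the list alone. The G2/M call was lost without anti-PD-L1 replicate 3 (adjusted p = 0.102). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 264 genes were higher and 831 lower (1095, 4332 at unadjusted p under 0.05). Against these stood 979 and 1380 by DESeq2, 156 and 203 by limma on log2(TPM + 1) and 5 in a fit of the 2 groups alone. Of the calls, 166 were pseudogenes (16.7% of those tested, against 6.6% of protein-coding genes). All 3 combination libraries belong to set P and all 3 anti-PD-L1 libraries to set Q, so added swainsonine and library set cannot be told apart here. Leaving out combination replicate 1 gave 244, replicate 2 gave 545 and replicate 3 gave 2975. Leaving out anti-PD-L1 replicates 1, 2 and 3 gave 640, 387 and 314. With limma on log2(TPM + 1) the median over all genes was 0.12 higher, or 0.16 on log2(TPM + 0.1).

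What did the combination add to swainsonine alone? T cell markers rose, with Cd27 at 3.29 ± 0.76, Cd247 at 3.66 ± 0.89 and Lck, the kinase that starts T cell receptor signalling, at 1.46 ± 0.37. Cd4 rose by 3.12 ± 0.84 (adjusted p = 0.0374, n = 3 each). Cytotoxic effectors rose with Tbx21 (4.27 ± 1.11) and Ccl5 (2.45 ± 0.65). The genes Lag3 (3.62 ± 0.68), Tnfrsf4 (2.19 ± 0.45) and Foxp3 (2.76 ± 0.69) rose, but Cd8a (4.03 ± 1.48, adjusted p = 0.0926) did not pass. The hypoxia genes Bnip3 (-1.51 ± 0.40), Pdk1 (-0.97 ± 0.27) and Ero1l (-1.87 ± 0.54) fell. So did the neutrophil genes S100a8 (-4.95 ± 1.18) and S100a9 (-4.35 ± 1.10) and all 8 red blood cell markers (median -5.21, Slc4a1 -5.24 ± 0.90). The endothelial genes Eng (0.91 ± 0.22) and Robo4 (1.09 ± 0.27) rose. Tmem109 rose to 120 ± 11.4 from 59.4 ± 8.11 CPM (1.02 ± 0.13, adjusted p = 0.00335). Ranbp2 (-1.17 ± 0.13), Snx13 (-1.26 ± 0.12) and the phospholipase gene Pnpla8 (-1.12 ± 0.12, adjusted p = 0.00177) fell, and each of these 4 genes had its groups apart with no overlap. By camera adjusted p was 1.42e-10 for T cell markers, 7.22e-09 for cytotoxic effectors, 0.000230 for endothelial markers and 2.40e-06 for red blood cells, each with adjusted p = 0.479 with an estimated correlation. By fry the red blood cell list had adjusted p = 0.0431. With a replicate block 0 lists passed fry, and likewise without combination replicates 1 or 2 or swainsonine replicates 1 or 2. Without combination replicate 3 there were 5 and without swainsonine replicate 3 there were 14. Hypoxia had a median of -0.71 (camera, adjusted p = 0.0287, with adjusted p = 0.703 with an estimated correlation). It was lost without swainsonine replicate 2 (adjusted p = 0.556), combination replicate 2 (adjusted p = 0.161) or combination replicate 3 (adjusted p = 0.0729). Of 21 T cell markers 10 were called over all genes and 19 when adjusted over the list alone, of 17 cytotoxic effectors 5 and 12, and of 19 hypoxia genes 3 and 3. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 534 genes were higher and 1244 lower (1778, 5063 at unadjusted p under 0.05). Other fits gave 1467 and 1804 by DESeq2, 503 and 217 by limma on log2(TPM + 1) and 2 in a fit of the 2 groups alone. Of the calls, 183 were pseudogenes (18.4% of those tested, against 11.3% of protein-coding genes). All 3 combination libraries belong to set P and all 3 swainsonine libraries to set Q, so added anti-PD-L1 and library set cannot be told apart here. Leaving out swainsonine replicates 1, 2 and 3 gave 521, 548 and 3012. Leaving out combination replicates 1, 2 and 3 gave 337, 989 and 3312. On log2(TPM + 1) the median over all genes was 0.16 higher, or 0.21 on log2(TPM + 0.1).

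Did swainsonine change the response to anti-PD-L1 in wild-type tumours? The difference of differences was negative for hypoxia response (19 of 19 below 0, median -1.29, Bnip3 -2.31 ± 0.56, Ero1l -2.93 ± 0.75) and red blood cell markers (8 of 8 below 0, median -4.66). It was positive for pigmentation (19 of 20 above 0, median 0.64), T cell markers (21 of 21 above 0, median 1.15) and endothelial markers (median 0.81, Robo4 1.34 ± 0.38). Hypoxia genes respond to oxygen supply, which red cells and vessels bring to a tumour. Man2a2 differed by 0.80 ± 0.27 (adjusted p = 0.183) and Gzmb by -0.96 ± 2.14. By camera adjusted p was 2.61e-05 for hypoxia and for pigmentation, 9.08e-05 for red blood cells, 4.78e-05 for T cell markers and 0.000705 for endothelial markers, each with adjusted p = 0.638 with an estimated correlation. Interferon gamma response was called up by camera (adjusted p = 0.000502, with adjusted p = 0.638 with an estimated correlation) with 14 genes above 0 and 13 below (median 0.06, mean -0.01). Mitochondrial transcripts were called down (adjusted p = 0.0372, with adjusted p = 0.638 with an estimated correlation) with a median of 0.01, opposite in sign. Over all genes 0 hypoxia genes and 0 T cell markers were called, and 8 and 0 when adjusted over the list alone. The combination libraries alone belong to set P, so this interaction holds the library set as well as the treatments. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 4 genes were higher and 16 lower (20, 2852 at unadjusted p under 0.05). Of these, 16 were pseudogenes, whose calls are uncertain (AC161763.1 -9.82 ± 0.54, Gm12261 -4.48 ± 0.43, Gm10156 -2.84 ± 0.43, Gm1821 1.71). A further 2 were protein-coding, with Snx13 at -1.16 ± 0.17 (adjusted p = 0.0387). With protein-coding genes only 0 were called (2358 at unadjusted p under 0.05), against 687 by DESeq2 over all genes and 9 by limma on log2(TPM + 1), 6 higher and 3 lower. Single left-out libraries gave 4 to 10 genes, except 1049 without combination replicate 3. With limma on log2(TPM + 1) the median over all genes was 0.22 higher, or 0.28 on log2(TPM + 0.1).

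Did the difference between libraries labelled knockout and Rosa26 follow the swainsonine effect? Under anti-PD-L1 by description, where Man2a1 was not lower in the libraries labelled knockout (0.58 ± 0.45), the 2 differences had a correlation of r = 0.092 across 15556 genes (Spearman -0.06). By title number, where Man2a1 differed by -1.36 ± 0.26, r was 0.401 (Spearman 0.368). In the IgG arms r was -0.045 by description and -0.148 (Spearman -0.132) by title number. Among the 1089 genes past the threshold in either comparison r was -0.539 by description and 0.476 (Spearman 0.48) by title number, so its sign depends on the labels. All of these were called for the combination against anti-PD-L1 alone, and 0 for the libraries labelled knockout or for swainsonine alone. All 3 combination libraries and no other wild-type library belong to set P, so that side of the correlation holds the set as well as swainsonine.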

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

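Tests of the sets of libraries, of the share of tumour cells, of lymph node and of Man2a1 order were chosen only after the results were seen, while the correlation of cultured and tumour effects, those of the pseudogenes and protein-coding calls and the regroupings were written down before. A difference between groups by interaction test set apart 3 results. Between tumours labelled knockout and Rosa26 by description, 13 gene lists responded to anti-PD-L1 to a different degree by camera. None did with an estimated correlation (adjusted p = 0.513 for interferon gamma response). The description did not separate Man2a1, at 72.6 ± 36.8 CPM in knockout and 73.2 ± 39.1 CPM in Rosa26, so these lists are not shown to depend on the knockout. By title number 17 lists were higher and 2 lower by camera, and 0 passed with an estimated correlation. By description, without knockout IgG replicate 3 the lists were 19 higher and 3 lower, and without knockout anti-PD-L1 replicate 3 they were 6 higher and 1 lower. Between swainsonine and PBS in wild-type tumours, 20 genes responded to anti-PD-L1 to a different degree by edgeR, 16 of them pseudogenes and 0 left when only protein-coding genes were tested. In the same test 19 gene lists differed by camera, with adjusted p = 0.638 with an estimated correlation for hypoxia response. The combination libraries alone belong to set P, so the set cannot be told apart from the treatments in this test.

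For T cell and cytotoxic genes in the combination group, 1 possible biological reading is that anti-PD-L1 with swainsonine brought more T cells into the tumour, which was not tested here. The library set of the combination group remains an open alternative, since all 3 combination libraries and no other wild-type library belong to set P. The set P library among the guide tumours, Rosa26 IgG replicate 1, held the 29 called genes at a median of -0.63 log2 against the 2 other controls of its group, with 26 of 29 lower. Such genes lay near the floor there, with Cd3e and Gzmb at 0 CPM in replicate 1. The 2 other controls held 0.0307 and 0.120 CPM of Cd3e and 0 and 0.150 CPM of Gzmb. A set effect on T cell genes could hardly show at these levels. Those 2 controls belong to set R, whereas the IgG and PBS libraries belong to set Q, so this difference is not the one between sets P and Q. A single library also excludes nothing, so treatment and set cannot be told apart. A lower share of tumour cells alone would raise markers of every other cell type alike. Red blood cell markers had a median of -3.275 with 8 of 8 below 0, which argues against such a uniform rise. Medians lay above 0 for muscle (4.232), macrophages (2.215) and adipocytes (1.585), and near 0 for keratinocytes (-0.123). Hbb-bs also varied within a group, from 1039 to 8175 CPM with swainsonine alone. Genes of the tumour cells were mixed. Tyr stood at 582 to 685 CPM in the combination against 892 to 1034 CPM with IgG and PBS. Dct overlapped, at 5389 to 8658 against 7463 to 8155 CPM, and the pigmentation list had a median of 0.04. A lower share beside other changes is therefore not excluded. Lymph node carried over would raise B cell markers with T cell markers, and the B cell list had a median of 0.584 against 4.201 for T cell markers, a gap of 3.62 against a spread of 1.72 among its members, which argues against it.

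For Man2a1 in the guide tumours, mislabelled columns were set against knockout cells that kept the transcript. By title number 0 libraries lay on the wrong side of the 6 highest and 6 lowest for Man2a1, against 6 by description. Over 233 genes other than Man2a1 with unadjusted p under 0.01 in culture, the cultured effect and the tumour effect had a correlation of r = 0.40 by title number and -0.02 by description (Spearman 0.46 and -0.08), which goes with columns given to the wrong libraries by description. If knockout cells had merely kept the transcript, control libraries would have stayed at their IgG level, but the highest of the 3 anti-PD-L1-treated libraries described as control held 59 CPM, below the lowest IgG control at 94.4 CPM, which argues against it. The description may therefore hold the error for 7 libraries, which only the submitters can settle.

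For pseudogenes among the calls of the combination group, the library set was weighed, and neither reads shared with related genes nor a biological explanation was tested. Over 214 called pseudogenes the combination effect and the difference of the set P control library had r = 0.12, or 0.20 over 216 with the 2 pseudogenes that define the sets, which were left out after that value was seen. Over 2198 called protein-coding genes r was -0.39. The prediction written for no effect of the set was r at or below 0.1, and it was not applied, because it rests on a single library that was itself low in immune transcripts and so differed in composition. That library was also compared with libraries of set R, whereas the combination was compared with libraries of set Q. These r values therefore do not measure the difference between sets P and Q. The library set remains open for both, and the treatment cannot be told apart from it.

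Regrouping the same samples gave 10 splits per pair of groups, too few for a share under 0.05. The real split gave 2557 genes for the combination against IgG and PBS, 1095 against anti-PD-L1 alone and 1778 against swainsonine alone, and the highest other split gave 0, 0 and 4, so 1 of 10 splits reached each real count. For the other comparisons of 2 groups the real split gave 0 genes, which 10 of 10 splits reach by construction, and the highest other gave 0, except 1 for knockout against Rosa26 under anti-PD-L1 and 184 for knockout with anti-PD-L1 against Rosa26 with IgG. The split with 184 set Rosa26 IgG replicate 1 and knockout anti-PD-L1 replicates 1 and 3 against the rest, which is sets P and Q against set R, so this split follows the library sets. With the library set as a covariate the real comparison gave 0 genes. For the interaction of knockout and anti-PD-L1 60 of 60 splits reach the real 0 by construction, with a highest other of 0, so they say nothing about chance. For the interaction of swainsonine and anti-PD-L1 2 of 60 splits reached the real 20, the real one among them, and the highest other split gave 1161, many times the real count. The other splits of both interactions were drawn at random, so 2 of 60 is an estimate and not an exact share. Why that split gave so many genes was not tested.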

How the results depend on the processing

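Calls and directions under the alternatives are given by setting, and except where stated the cause was not tested. For the leading genes of the combination comparisons, directions held in all fits. By DESeq2 the counts were 69 in culture, 500 for knockout under IgG, 1 for anti-PD-L1 in Rosa26 tumours, 118 in knockout tumours, 139 for knockout with anti-PD-L1 against Rosa26 with IgG, 4 for anti-PD-L1 and 18 for swainsonine in wild-type tumours, and 3855, 2359 and 3271 for the combination against IgG and PBS, anti-PD-L1 alone and swainsonine alone, with 687 for the interaction of swainsonine and anti-PD-L1. By edgeR the first 7 of these were 0, and the last 4 were 2557, 1095, 1778 and 20. With no filter the counts were 2 in culture, 3 for knockout under IgG, 41 for anti-PD-L1 in knockout tumours and 30 for knockout with anti-PD-L1 against Rosa26 with IgG. With a replicate block they were 56 in culture, 2 for knockout with anti-PD-L1 against Rosa26 with IgG, and 1667, 490, 745 and 5 for the combination comparisons and the interaction. The replicate numbers do not pair samples: the correlation of same-number differences was -0.05 in culture, -0.37 to 0.70 in guide tumours (11 of 18 over 0.1), -0.41 to 0.53 by title number (6) and -0.63 to 0.63 in wild-type tumours (9 of 18). On log2(TPM + 1) and log2(TPM + 0.1) the counts were 1 and 1 for swainsonine, and 974 and 893, 359 and 336, 720 and 639, and 9 and 7 for the combination comparisons and the interaction, with fewer genes tested. Requiring an absolute log2 fold change of at least 1 left 1172, 491 and 792 by its construction. With only the 2 groups compared the counts were 31 for knockout under IgG, 1 for knockout under anti-PD-L1, and 5 and 2 for the combination against anti-PD-L1 alone and swainsonine alone, with fewer samples for the dispersion. With protein-coding genes only the interaction of swainsonine and anti-PD-L1 fell to 0 genes. Leaving out single libraries gave 15 to 4125 genes in culture, where each fit left an arm of 1 library with the spread of the other pair alone. In tumours it gave 0 to 88 for knockout under anti-PD-L1, 0 to 35 for anti-PD-L1 in knockout tumours, 0 to 149 for knockout with anti-PD-L1 against Rosa26 with IgG, 598 to 3972, 244 to 2975 and 337 to 3312 for the combination comparisons, and 4 to 1049 for the interaction. By title number edgeR called 1 gene for anti-PD-L1 in knockout tumours, and the 5 libraries with 1 group in both readings gave 1 for knockout with anti-PD-L1 against Rosa26 with IgG. DESeq2 by title number called 5 and 222 for knockout under IgG and anti-PD-L1, 518 and 115 for anti-PD-L1 in Rosa26 and knockout tumours, 247 for knockout with anti-PD-L1 against Rosa26 with IgG and 2 for the interaction. Of 334 gene list tests 159 passed by camera, 5 by fry and 0 with an estimated correlation, which allows for correlated genes by construction. Lists that reversed by title number, with their camera adjusted p, and with the library set added where that also reversed, were G2/M (0.745, 0.526) and cholesterol (0.778, 0.114) for knockout under IgG, interferon gamma (0.596), MHC class II (0.596, 0.955) and macrophage and monocyte markers (0.773, 0.000184) for anti-PD-L1 in Rosa26 tumours, G2/M (0.365, 0.356), hypoxia (0.0635, 0.122) and cholesterol (0.0354) for anti-PD-L1 in knockout tumours, and cholesterol (0.884, 0.00505) for the interaction. Only with the library set added by title number, muscle (0.795) and hypoxia (0.795) reversed for anti-PD-L1 in Rosa26 tumours and muscle (0.977) in knockout tumours. With the library set as a covariate by description, mitochondrial transcripts reversed for knockout under IgG (0.189) and for knockout with anti-PD-L1 against Rosa26 with IgG (0.697, and 0.475 by title number). Leaving out knockout IgG replicate 1 reversed endothelial markers in the interaction of knockout and anti-PD-L1 (0.991, range of left-out libraries 7.72e-06 to 0.991), and leaving out anti-PD-L1 replicate 1 reversed type I interferon response for anti-PD-L1 in wild-type tumours (0.977, range 2.91e-09 to 0.977). The correlation of the difference between libraries labelled knockout and Rosa26 with the swainsonine effect was 0.092, against 0.401 by title number, -0.045 in the IgG arms, -0.539 over genes past the threshold in either and 0.035 with no filter. By title number it was -0.148 in the IgG arms and 0.476 over genes past the threshold in either, neither of which was planned. The effect of depth was not tested.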

Other observations

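The interferon gamma list stood at 1.93, 0.70 and 5.70 (mean log2 CPM) in the 3 swainsonine tumours, at 5.76, 4.72 and 1.23 with anti-PD-L1, and at 6.37, 5.92 and 6.19 with both. Among guide tumours Rosa26 anti-PD-L1 replicate 2 by description held 9380 CPM of Hbb-bs, and the interferon gamma list stood highest, at 5.08 and 4.65, in knockout anti-PD-L1 replicates 2 and 3, which keep their group in both readings. The fat cell gene Adipoq reached 15.1 CPM in swainsonine replicate 1.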
